A study of Mus musculus with 84 samples.

How the data were processed

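The series holds single-cell RNA sequencing of 84 cells from the aorta-gonad-mesonephros (AGM) region of E11.5 mouse embryos, where E counts embryonic days. The AGM is the trunk region that holds the dorsal aorta and the primitive kidney. Per the labels, cells were sorted for the endothelial surface proteins CD31 (Pecam1) and CD144 (Cdh5) and against CD41 (Itga2b) and CD45 (Ptprc). They were captured on a microfluidic chip for cells of 10 to 17 µm, and full-length cDNA was made with a SMARTer kit. Libraries were prepared with Nextera XT, pooled at 24 per lane and read single-end at 67 bp on a HiSeq 2500, per the labels' protocols. Each sample of the series is 1 cell. No embryo or pool is named for any cell, so the 84 cells form 1 group that counts as 1 sample, and no test across cells was run.

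The deposited table gives TPM (transcripts scaled to a fixed total per cell) for 20308 genes in each of the 84 cells, and the columns sum to between 999998 and 1000002. The submitters' processing notes name CASAVA 1.8.2, RSEM 1.2.3, Bowtie 0.12.9 and the mouse genome build mm10. Their order and settings and the gene annotation are not given in the sources used here. TPM keeps no sequencing depth, so the number of reads behind each cell is unknown, and a value of 0 in a cell can mean absence or a transcript missed in capture. The table holds 0 mitochondrial and 0 spike-in rows, so neither could be used to judge cells. Of the gene symbols, 18956 (93.3%) matched a symbol of the RefSeq annotation of GRCm38.p6, the assembly that mm10 names, and coordinates come from that annotation. Values of near-identical genes (Ccl21a and Gm13304, Hba-a1 and Hba-a2, Hspa1a and Hspa1b, and Y-linked genes beside their X-linked relatives) depend on how shared reads were divided and are uncertain.

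The following choices were made before the data were examined. Cells with under 1000 genes at TPM 1 or more would have been left out, and 0 cells were. A gene was called detected in a cell at TPM 1 or more, and a marker of another cell type was counted at TPM 10 or more. Shares of cells carry exact Clopper-Pearson intervals at the 95% level, which cover counting error over cells only. For a count of 0 of 84 cells the upper end of that interval is 4.30%, which limits the share of cells in which a transcript is detected, not the share that expresses the gene. Genes detected in at least 5 cells (12318 genes) entered scores and clustering as log2(TPM + 1), a scale that understates differences of low genes.

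Fixed gene lists numbered 21 with 223 genes, of which 220 were in the table; Xist, Hbb-b1 and Hbb-b2 had no row. They were named sort gate, pan-endothelial, arterial, venous, lymphatic, tip or angiogenic, hemogenic, flow response, matrix and mural recruitment, cell cycle S, cell cycle G2M, erythroid, macrophage, megakaryocyte or platelet, mesenchyme, smooth muscle, epithelial or mesonephric, neural or sympathetic, trunk Hox, sex-linked, and stress or dissociation. A list score is the mean log2(TPM + 1) of a list in a cell minus the mean of unlisted genes from the same 20 bins of mean expression. The SD of the score over cells was placed as a percentile among 10000 random lists of the same size, matched on mean expression. Lists with under 3 genes detected in 5 cells were not scored. Opposition of arterial and venous genes was measured as the SD of the arterial minus the venous score over the SD of their sum, both scaled to SD 1, and placed among 10000 random pairs of lists. These percentiles describe 84 cells and are not p-values. The random lists were not matched on the SD of single genes. A list of singly variable genes can therefore reach a high percentile without its genes varying together. Co-detection was counted for 20 pairs of 5 arterial and 4 venous genes beside the number of cells that independent detection gives.

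Cells were clustered by Ward's method on 10 principal components of the 1000 genes with the largest SD for their mean, with all listed genes left out. The number of clusters, from 2 to 6 with at least 5 cells each, was the one with the highest mean silhouette. No doublet caller was run, since 84 cells from a chip give it too little to work on, and doublets are weighed in the closing observations. The genes named in the text are the 4 sort gate genes, the 4 members of each list detected in the most cells and the member detected in the fewest, the 10 leading genes of each cluster, the 10 unlisted genes with the largest SD for their mean, the 10 genes with the highest mean apart from mitochondrial and ribosomal protein genes, and every arterial and venous member for the clusters with the highest and lowest arterial minus venous score. Other genes named were chosen after their values were seen, and the text says so. Values of 2 list members that the rule takes are not reported here.

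The technical groupings in the labels are the first and the second index of each library's barcode. The second splits the cells into 7 sets of 12, which are the index sets of the text. The first, with 12 sequences, was used only in a closing test of shared reads. The lane of each library is not given in the sources used here. Alternatives changed the cell and gene filters, the pseudocount (0.1 and 10), the scaling (a median-of-ratios factor per cell), the detection and marker minimums, the clustering method and its genes, the cells used, and the centring of index sets. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

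The procedures were tested on simulated data made by permuting each of the 12318 genes over cells. In data without structure, 6.50% of 200 random lists passed the 95th percentile, and 5.00% of 200 random lists did so in the real data. Both shares set random lists against random lists, so they check the calculation only and not how chosen marker lists behave. A shared factor of 0.25 SD added to 20 genes put the list above the 95th percentile in 100% of 50 simulations, and an opposed factor of that size over 29 genes did so for the opposition ratio in 98.0%. Permuting removes the variation that genes share, so these 2 recovery values may not carry over to the real data. With 12 cells raised in 200 genes, the mean adjusted Rand index between true and found clusters was 0.964 at a log2 difference of 4, 0.0065 at 2 and -0.011 at 1. In these permuted data the clustering therefore found only groups with large differences. How far this carries over to the real data, where genes vary together, is not known.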

Results

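Transcriptomes were measured in 84 single endothelial-sorted cells of the AGM of E11.5 mouse embryos, given as TPM. A median of 6978 genes reached TPM 1 per cell, with quartiles of 6532 and 7406 and a range from 3334 to 10073. Zeros made up 57.6% of all values, and 1219 genes were above 0 in every cell. The 100 highest genes of a cell held a median of 30.2% of its TPM, from 25.1% to 43.4%. The highest correlation between any 2 cells was 0.817, and 0 pairs were identical. Since the cells form 1 sample with no named embryo, values are descriptions of these cells without a replicate error. The cytoskeletal gene Actb had the highest mean level, with a median of 15697 TPM, followed by the elongation factor Eef1a1 (10211 TPM) and the ubiquitin gene Ubb (9125 TPM). Actg1, Hspa8, Ppia, Ftl1, Sept2, Tmsb4x and Npm1 completed the 10 highest, with medians between 3638 and 7016 TPM.

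The first question was whether transcripts followed the sort. Pecam1, which encodes CD31 (chromosome 11, 106654213 to 106715281), was detected in 80 of 84 cells, or 95.2% (95% interval 88.3% to 98.7%), with a median of 152 TPM. Cdh5, which encodes VE-cadherin (chromosome 8, 104101613 to 104144504), was detected in 82 cells, or 97.6%, with a median of 140 TPM. Of the genes sorted against, Ptprc (CD45) was detected in 0 cells, and Itga2b (CD41) in 7 cells, or 8.33% (3.42% to 16.4%). Only 2 of these 7 cells held Itga2b at TPM 10 or more, with a maximum of 686 TPM. All 17 pan-endothelial genes were detected in 60 or more cells, led by Kdr, a receptor for VEGF (83 cells), the transcription factors Fli1 and Ets1 (82 cells each) and Egfl7 (81 cells), with Sox18 (60 cells) at the low end. A median of 15 of the 17 reached TPM 10 per cell. The pan-endothelial score varied more over cells than all 10000 matched random lists, with an SD 2.93 times their median, and the sort gate score lay at percentile 95.7.

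The series title concerns arterial endothelium, so arterial and venous genes were examined next. Venous genes and the more broadly expressed arterial genes were detected in most cells, with a median of 5 of 21 arterial and 7 of 9 venous genes at TPM 10 per cell. Of the arterial list, the ephrin ligand Efnb2 and the co-receptor Nrp1 were each detected in 78 of 84 cells, Notch1 in 76 and Epas1 in 72. Genes regarded as more restricted to arteries were found in fewer cells: Sox17 in 37, the Notch ligand Dll4 (chromosome 2, 119325784 to 119335666) in 29, the connexin Gja4 (chromosome 4, 127311420 to 127314039) in 23, Gja5 in 8 and Hey2 in 4. Levels could still be high, with up to 1719 TPM for Gja4 and 110 TPM for Dll4. The venous regulator Nr2f2 (chromosome 7, 70351946 to 70366746) was detected in all 84 cells, with a median of 156 TPM, and reached TPM 10 in 82. Emcn was also found in all 84 cells, at a median of 925 TPM, Nrp2 in 81, Flrt2 in 77 and Ephb4, the receptor for Efnb2, in 72, while Stab2 was found in 31. All 84 cells held at least 3 venous genes at TPM 10, the 12 mesenchyme-like cells described further on among them. In those 12, 7 of the 9 venous genes had a lower mean, but Nr2f2 had a median of 174 TPM against 151 in the other cells. The venous counts are therefore not ones of venous endothelium alone.

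**Figure D1:**
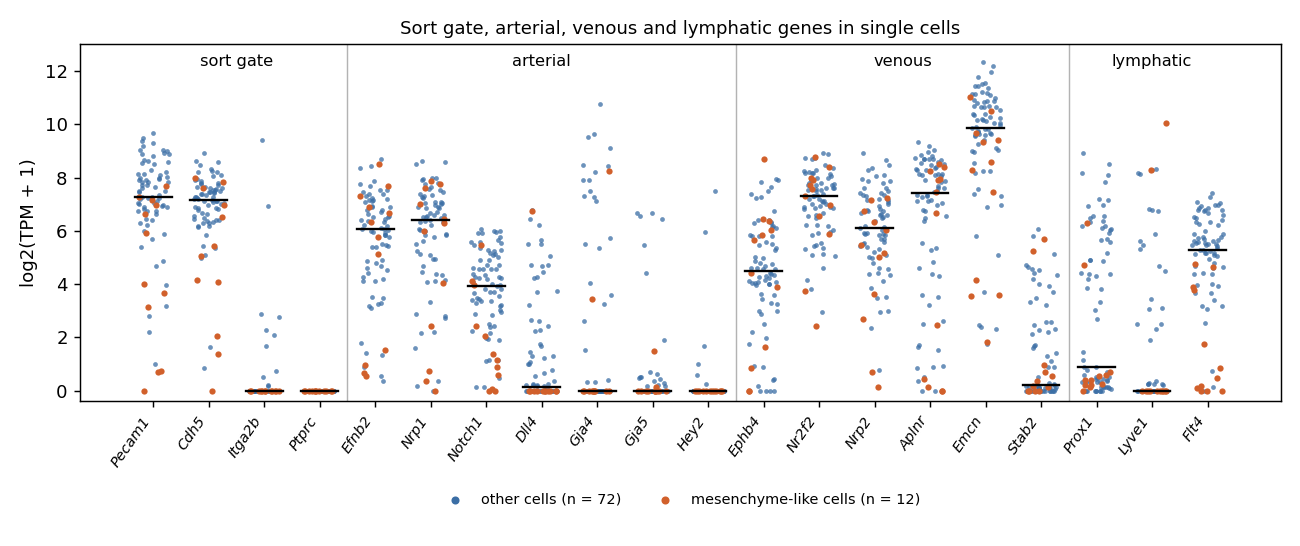
Expression of sort gate, arterial, venous and lymphatic genes in each of the 84 cells, as log2(TPM + 1). Each point is 1 cell, the black bar is the median over all cells, and orange points are the 12 mesenchyme-like cells; Nr2f2 and Emcn lie above 0 in every cell, while Gja5 and Hey2 lie at 0 in most.

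Cells with arterial genes held venous genes about as often as cells at large. Of the 23 cells with Gja4, 20 held Aplnr, where independent detection gives 19.99, and of the 29 with Dll4, 27 held Ephb4, against 24.9. Over 20 arterial and venous gene pairs, the number of cells with both genes was a median of 1.01 times that given by independent detection, from 0.987 to 1.17. The 4 venous genes of the pairs were detected in 72 to 84 cells at TPM 1. Nr2f2, found in all 84, has its pairs fixed at 1, and the ratio of a median pair had no room below 0.808. At TPM 10 the observed median was 1.02 (0.918 to 1.38), but 6 of the 20 pairs, among them all 4 with Efnb2, could still not fall below 0.8. The pairs with more room rest on few cells, with Dll4 in 16 cells, Gja4 in 19, Gja5 in 6 and Hey2 in 2, and the ratio of 1.38 is 2 cells with Hey2 and Ephb4 against 1.45. The arterial and venous scores each varied more over cells than all 10000 random lists, with SDs 1.76 and 1.69 times the random medians. The SD of their difference was 0.833 times the SD of their sum, at percentile 6.30 of random pairs, whose 95th percentile was a ratio of 1.22. On these values the 2 scores did not oppose each other more than random lists did. With 40 cells that hold markers of other cell types left out (erythroid markers were not used for this), the ratio was 0.988 and lay at percentile 47.2. Within the 7 index sets it ranged from 0.354 to 1.11. With the pan-endothelial score regressed out, an alternative chosen after the data were seen, it turned above 1, to 1.15 at percentile 87.6.

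**Figure D2:**
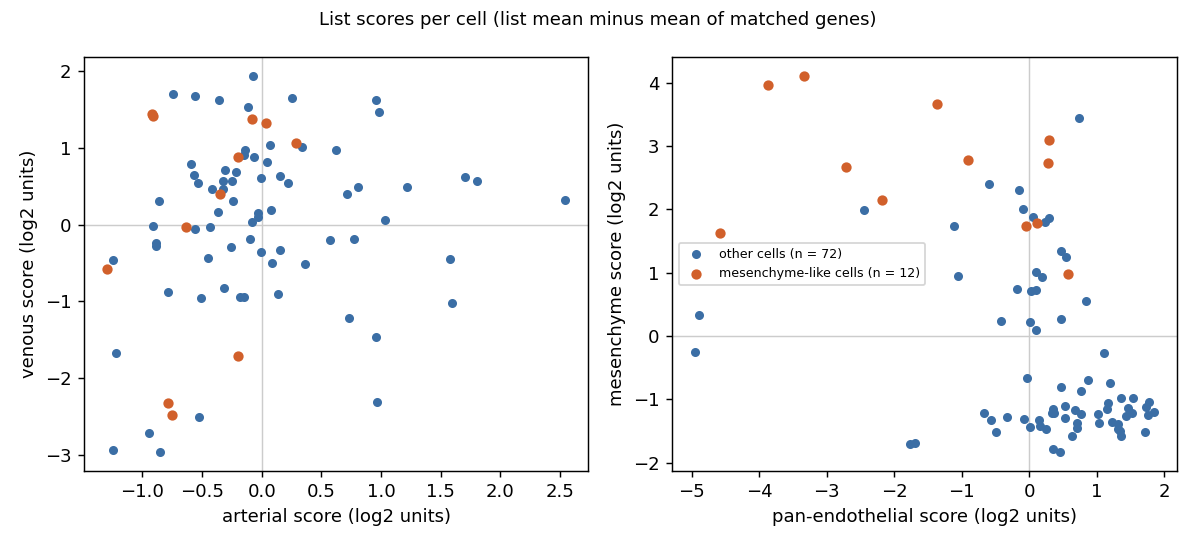
Left, arterial against venous score, and right, pan-endothelial against mesenchyme score, for each of the 84 cells, in log2 units relative to matched genes. Blue points are 72 cells and orange points the 12 mesenchyme-like cells, whose mean mesenchyme score was 2.61 against -0.44, with overlap between single cells.

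Lymphatic genes were also present in the sort. Flt4, the receptor for VEGF-C, was detected in 73 cells, Pdpn in 50, the lymphatic regulator Prox1 (chromosome 1, 190118035 to 190170827) in 41 and Lyve1 in 22. Prox1 reached TPM 10 in 36 cells. In the 12 mesenchyme-like cells described further on, the mean of Pdpn was 1.15 log2 units higher than in the other cells, and that of Lyve1 0.06 higher. The differences were -3.50 for Flt4 and -1.93 for Prox1. Pdpn was detected in 8 of those 12 cells, so its count is not one of lymphatic cells alone. The lymphatic score varied more than 99.98% of random lists, with an SD ratio of 1.44. Of the tip or angiogenic list, Nid2 was detected in 66 cells, Kcne3 in 60, Angpt2 in 56, Pdgfb in 41 and Esm1 in 16, and its spread exceeded all random lists (SD ratio 1.52). Of the flow response list, Klf6 was detected in 75 cells, Klf4 in 51, Thbd in 42, the nitric oxide synthase Nos3 in 35 and Cyp1b1 in 9, at percentile 99.84 (SD ratio 1.35). Basement membrane genes of the matrix and mural recruitment list were widespread, with Col4a1 in 84 cells, Sparc in 83, and Col4a2 and Lama4 in 82 each, while the elastin gene Eln was found in 4. That list lay at percentile 97.3 (SD ratio 1.24).

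Blood-forming endothelium arises in the AGM, so genes linked to it were counted. Neurl3 was detected in 84 cells, Cd34 in 80, Lmo2 in 77 and Etv6 in 63, and Gata2 and Kit in 55 and 58. Neurl3 lay at a median of 18.45 TPM, and its mean was 0.93 log2 units higher in the 12 mesenchyme-like cells. Of the 18 list genes, 13 had a lower mean there and 3 a higher one. Detection of Neurl3 in every cell therefore does not set blood-forming endothelium apart. Runx1, the regulator of the endothelial to blood transition (chromosome 16, 92601466 to 92826074), was detected in 10 cells and reached TPM 10 in 4. Gfi1b was detected in 4 cells, Myb in 5 and Hlf in 2, and Gfi1 and Spi1 in 0. The hemogenic score had an SD 1.18 times that of random lists, at percentile 95.35. The percentile was 86.1 without the 12 mesenchyme-like cells described further on, 60.4 without the 40 cells holding markers of other types, and 93.4 with a pseudocount of 10. Gata2, Kit, Runx1, Gfi1b, Myb and Hlf were singled out after their values were seen, as was Mki67 in the account of the clusters.

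Transcripts of proliferating cells were abundant. Of 16 cell cycle G2M genes a median of 12.5 reached TPM 10 per cell, and 67 cells held at least 8 of them. Birc5 was detected in 84 cells, Top2a and Ube2c in 83 each and Cenpf in 82, with Aurka and Aurkb lowest at 51. Of 14 cell cycle S genes a median of 12 reached TPM 10, with Tyms in 84 cells, Pcna and Rrm1 in 83, Mcm3 and Mcm5 in 82 and Ccne1 in 41. The G2M score had the largest spread of the scored lists relative to random lists, with an SD ratio of 3.46, and the S score had 2.14. Both exceeded all 10000 random lists. Several genes of the stress or dissociation list were detected in most cells, with Jun in 81 cells, Hspa1b in 78, Dusp1 in 71, Ier2 in 70 and Hspa1a in 14 (SD ratio 1.51, above all random lists). Hspa1b was low, with a median of 4.6 TPM and TPM 10 or more in only 10 cells.

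Trunk Hox genes, which mark position along the body axis, were detected in 80 cells at 1 or more of 14 genes, with a median of 4 per cell. Hoxa5 was detected in 39 cells, Hoxd8 in 37, Hoxa9 in 36, Hoxa7 in 35 and Hoxb8 in 2, and the spread exceeded all random lists (SD 0.750 against a random median of 0.501). Of the Y-linked genes, Ddx3y was detected in 68 cells, Eif2s3y in 64, Uty in 49 and Kdm5d in 39. At least 3 of these 4 genes were detected in 52 cells and none in 6 (SD ratio 1.55, above all random lists).

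**Figure D3:**
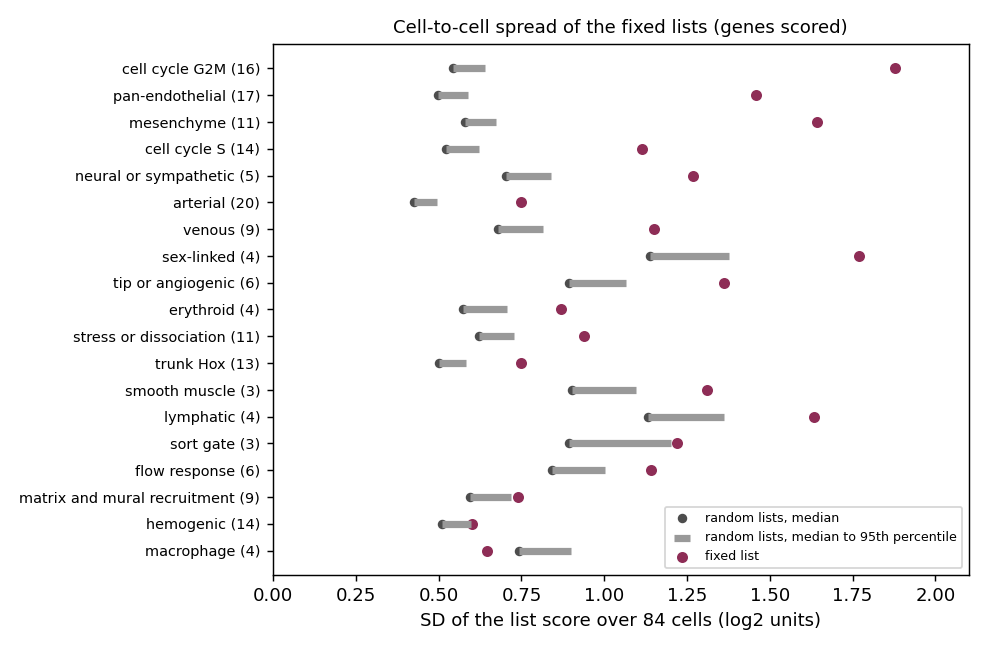
SD over 84 cells of the score of each list with 3 or more scored genes (number of genes in parentheses), in log2 units. Grey points and bars are the median and the 95th percentile of 10000 random lists matched on mean expression. Of 19 lists, 18 lie above the 95th percentile, where 0.95 would if the lists were random draws. The fixed lists are markers, and the SD of single genes was not matched, so this count does not show that their genes vary together.

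Clustering without the listed genes split the cells into 72 and 12 (14.3%, 7.61% to 23.6%), with a mean silhouette of 0.287 against 0.121 or less for 3 to 6 clusters. The 12 cells were mesenchyme-like. All 11 mesenchyme genes, among them collagens and transcription factors of connective tissue, had a higher mean in these cells by over 1 log2 unit, with a median difference of 2.69. Col1a2 differed by 5.09 (median 172 against 0.22 TPM), Prrx1 by 4.65, Col3a1 by 4.22 and Col1a1 by 4.08, and the least detected member, Dcn, by 1.29. The other leading genes were Crabp1 (6.70), Crabp2 (6.22), Meis1 (5.03), Sfrp1 (4.99), Igfbp5 (4.97), Gpc3 (4.84), Lpar1 (4.69) and Ptn (4.42), which defined the cluster. Of the genes higher in the other 72 cells, Tubb6, Tmem204, Cotl1, Grap, Crip2, Bcl6b, Rhoj, Plau, Gchfr and Dusp3 led, with differences between 4.15 and 5.83. Under other clustering settings the mesenchyme-like cluster held from 9 to 36 cells, and as few as 9 of the 12 stayed in it, so its border was not sharp.

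Endothelial genes were lower on average in the mesenchyme-like cells. All 17 pan-endothelial genes had a lower mean, 16 of them by over 1 log2 unit, with a median difference of -2.44, against -0.28 for all 12318 genes. A median of 7.5 of the 17 genes reached TPM 10, with a range from 0 to 15, compared with 15 in the other cells. The 12 cells were not alike: their pan-endothelial scores ran from -4.59 to 0.58, with 5 cells 2 or more log2 units under the mean of the other cells (0.29) and 5 cells within 1 unit of it or above, so the former carry most of the difference. Both Pecam1 and Cdh5 reached TPM 10 in 8 of the 12. G2M genes were higher in 14 of 16 cases (15 after median-of-ratios scaling), by a median of 0.55, with Aurka 1.84 and Mki67 1.88 higher, and 13 of 14 S genes were lower (10 after that scaling), but their median of -0.33 (-0.25) lay near that of all genes (-0.28 and -0.24), of which 7999 of 12318 were lower. The stress or dissociation score was 0.62 in the 12 cells and -0.10 in the others, with 6 of 11 genes higher, among them Egr1 by 2.05 and Fos by 1.67, both named after their values were seen. The 12 cells had a median of 6153 detected genes, and the 72 had 7049.

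The mean arterial minus venous score was -0.013 in the 72 cells and -0.55 in the 12 mesenchyme-like cells. Among these 12 the arterial score lay above the venous score in cells 13, 14 and 65 and below it in the others, so -0.55 is a mean over unlike cells. Of 21 arterial genes 19 had a lower mean in the mesenchyme-like cells. The differences were -2.52 for Unc5b, -2.07 for Notch1, -1.58 for Epas1, -1.12 for both Nrp1 and Sox17 and -1.07 for Acvrl1. Gja4 was lower by about 1 log2 unit, and the differences were -0.95 for Hey1, -0.92 for Dll4, -0.90 for Notch4 and -0.78 for Efnb2. They lay between -0.56 and -0.01 for Cxcr4, Jag2, Jag1, Gja5, Bmx, Hey2, Heyl and Tmem100. Vegfc was 1.14 and Nt5e 0.13 higher. Of 9 venous genes 7 were lower, by -2.25 for Stab1, -2.12 for Emcn, -1.48 for Aplnr, -1.43 for Nrp2, -0.24 for Stab2, -0.23 for Nr2f2 and -0.23 for Ephb4, while Dab2 was 1.72 and Flrt2 0.72 higher. The venous median of -0.24 lay near that of all genes, and the venous score, which is set against matched genes, was on average 0.03 higher in the mesenchyme-like cells. Their venous scores ran from -2.48 in cell 65 to 1.44 in cell 54, so this mean blends unlike cells.

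Few cells held 3 or more markers of a cell type other than mesenchyme at TPM 10, though single markers were more widespread. At least 3 mesenchyme markers reached TPM 10 in 34 cells, 22 of them outside the mesenchyme-like cluster, and 11 cells passed at TPM 100. The same count was 3 cells for erythroid genes, 1 for macrophage, 3 for megakaryocyte or platelet, 1 for smooth muscle, 2 for epithelial or mesonephric and 4 for neural or sympathetic genes. Most detected were Alas2 (14 cells), Hba-a1, Hbb-y and Hba-a2 (6, 6 and 5) among erythroid genes, with Slc4a1 in 0. Macrophage genes were led by Cx3cr1 (47 cells, all at 6.42 TPM or less), Mrc1 (12), Fcer1g (11) and Cd68 (9), with C1qb in 0. Pf4 was detected in 18 cells, Gp1bb in 8, Ppbp and Gp9 in 3 and Gp6 in 2. Tagln was detected in 14 cells, Acta2 in 12, Rgs5 in 9, Cnn1 and Actg2 in 2 and Myh11 in 0. Epcam was detected in 7 cells, Wt1 in 6, Krt18 in 4, Cdh1 and Lhx1 in 3 and Krt8 in 0. Stmn2 was detected in 25 cells, Elavl4 in 21, Tubb3 in 12, Sox2 in 10 and Th in 0. SD ratios were 1.51 for the erythroid list (percentile 99.89), 0.867 for macrophage (percentile 15.6), 1.45 for smooth muscle (percentile 99.99) and 1.81 for neural or sympathetic and 2.84 for mesenchyme, both above all random lists. The megakaryocyte or platelet and the epithelial or mesonephric lists had too few detected genes to be scored.

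Outside the lists, the chemokine gene Ccl21a had the largest SD for its mean, with detection in 22 cells and up to 5853 TPM, followed by its near-identical copy Gm13304 (18 cells). The muscle regulator Myog was detected in 5 cells at up to 2380 TPM, and Dppa5a, a gene of pluripotent and germ cells, in 8 cells at up to 3902 TPM. Ldhb, Crabp2, Madcam1, Crabp1, Agtr2 and S100a16 completed the 10, in 65, 44, 46, 27, 5 and 80 cells.

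Across the 7 index sets of 12 cells, Pecam1 was detected in 10 to 12 cells, Cdh5 in 11 or 12, Itga2b in 0 to 2 and Ptprc in 0. Mesenchyme-like cells occurred in 6 of the 7 sets, with at most 3 in any set. The arterial score passed the 95th percentile of random lists in 6 of 7 sets, the venous in 5, the hemogenic in 2 and the G2M in 7.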

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

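Both cell filters removed 0 cells, which fixed 40 of the 150 alternative values. Of the other 110, 88 stayed within the counting error of the reported value or on its side of the percentile limit, 19 moved and 3 lost the percentile. The opposition percentile counts among the 88, although it went from 6.30 to 47.16 without cells of other types and to 87.63 with the pan-endothelial score regressed out. The alternatives without the mesenchyme-like cells, with the pan-endothelial score regressed out and with 4 clusters were chosen after the data were seen. Pecam1 was above 0 TPM in 98.8% of cells, and Itga2b reached TPM 10 in 2.38%. With markers counted at TPM 1, macrophage markers rose to 8 cells, smooth muscle to 2 and neural or sympathetic to 10. At TPM 100 they fell to 0 for erythroid, macrophage, smooth muscle and epithelial or mesonephric genes, 1 for megakaryocyte or platelet, 2 for neural or sympathetic and 11 for mesenchyme; without the mesenchyme-like cells 22 cells held mesenchyme markers. The hemogenic percentile was 93.4 with a pseudocount of 10, 60.43 without cells of other types (44 cells used) and 86.08 without the mesenchyme-like cells, and the cause was not tested. The mesenchyme-like cluster held 36 cells without the filter on low genes, 28 with k-means, 31 with 500 variable genes and 21 with listed genes kept in; the last shared 11 of the 12 cells, the others all 12. It held 18 cells with a pseudocount of 10, which shared all 12, and 17 with median-of-ratios scaling, 10 with 2000 variable genes and 9 with a pseudocount of 0.1, each of which shared only 9 of the 12. A fixed number of 4 clusters gave 4. Sequencing depth is unknown, so detection of low genes cannot be separated from capture losses.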

Other observations

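The 4-cluster look, the gene pairs, and the germ, muscle and neural genes of this part were chosen after the values were seen. So were the tests of cells without endothelial transcripts, of library batch for the mesenchyme-like cells, of endothelial reads from other libraries of the same index set, and of a mixture with any cells holding markers of another type. The restriction to cells of equal RNA content was also added to a doublet test afterwards, and so was the requirement of separate intervals in the tests of shared reads, without which both ratios would have counted for shared reads. The reading of that doublet test cell by cell was added afterwards as well; on the mean alone it would have excluded pairs of equal content. A division into 4 clusters (39, 26, 12 and 7 cells, mean silhouette 0.121) kept the 12 mesenchyme-like cells and set apart 7 cells with a lymphatic score 2.55 log2 units above the others. Prox1, which was not used in clustering, had a median of 144 TPM in these 7 cells and 0.61 in the remaining 77, and Nfatc1 had 137 against 6.13 TPM. Neither gene was confined to the 7 cells. Prox1 reached TPM 10 in 6 of the 7 and in 30 of the 77, Nfatc1 in 6 and 34, and Ccl21a in 5 and 15. Most cells with Prox1 at that level therefore lay outside the group. The lymphatic list member Lyve1 was not raised: it reached TPM 10 in 1 of the 7 cells and in 14 of the 77, with a median of 0 in both. Their G2M score differed from the others by -1.57, and Ccl21a, Lck and Gm13304 were among their leading genes. Over all cells, Prox1 and Ccl21a both reached TPM 10 in 19 cells, where independent detection of the 36 and 20 cells would give 8.57, while Prox1 and the venous and lymphatic gene Stab2 did so in 6 against 6.86. Gja4 and Gja5 met in 5 cells against 1.36, and Gja4 and Dll4 in 6 against 3.62, but Dll4 and Sox17 met in 2 against 2.29 and Gja5 and Dll4 in 1 against 1.14, among 18 pairs counted.

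Several cells held genes of lineages far from endothelium together with endothelial transcripts. Cell 41 held the platelet genes Pf4 at 35696, Ppbp at 10388 and Gp9 at 2425 TPM, Itga2b at 686 and the muscle genes Myog at 2380 and Actc1 at 3375, beside Pecam1 at 127 and Kdr at 190. The germ cell genes Dppa5a and Dppa3 reached 3902 and 3312 TPM in cell 79, 2763 and 2404 in cell 4 and 587 and 463 in cell 62, beside Kdr at 105, 219 and 111 TPM. Tubb3 reached 3333 TPM in cell 12, 2696 in cell 39 and 2004 in cell 61, and cell 39 held only 1 of 17 pan-endothelial genes at TPM 10. Cell 62 had the most detected genes, 10073, and held germ cell genes beside 14 pan-endothelial genes at TPM 10.

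The mesenchyme-like cells inside an endothelial sort are a first pattern to weigh. If each held an endothelial and a mesenchymal cell of equal RNA content, endothelial genes would lie about 1 log2 unit lower, and the median over 17 genes was -2.44, but that mean hides 5 cells 2 or more units lower and 5 within 1 unit of the other cells or above, so such pairs are not excluded for the cluster. Cells wholly without endothelial transcripts are argued against as the whole cause, since the median gene reached TPM 10 in 50% of the cells (quartiles 33.3% and 58.3%). Cell by cell, 9 of the 12 held at least 3 of the 17 genes at TPM 10, and the lowest held 0, so this does not cover every cell. It also takes the reads as each cell's own, and reads shared between libraries stay open below. A batch by second index is argued against too, since at most 3 of the 12 cells shared an index set, while a batch by lane or chip was not tested. The 12 cells had a median of 6153 detected genes, from 3334 to 8511, against 7049 in the other 72, from 5240 to 10073. They thus showed no surplus of genes, which 2 cells in 1 site could give. No bound was set for this count in this pattern, the ranges overlap and sequencing depth is unknown, so it does not exclude pairs. Pairs of cells, a mixture of cell kinds, or single cells that express both programmes stay open, and no biological explanation was tested, because the design names no group.

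In the pattern of other-lineage genes beside endothelial transcripts, the 12 cells with at least 3 markers of a non-mesenchymal lineage had a median of 7343.5 detected genes, against 6902 in the remaining 72, whose upper quartile was 7373, so doublets can be neither favoured nor excluded. Shared reads were looked for in 9 genes that reached TPM 500 in 1 cell and stayed under 5 in all others. That rule leaves out stronger sharing, and the genes came from only 5 cells, so their values are not independent. For these 9 genes, values above 0 were 2.18 times as frequent in the same second-index set (3 of 99 against 9 of 648) and 3.14 times with the same first index (2 of 54 against 7 of 594). Both ratios passed the bound of 2 set beforehand for shared reads, but on so few counts that their intervals overlap, so they do not decide. In 6 of the 12 cells, 10 or more endothelial genes lay at TPM 10 and over 10 times the lowest level of their index set, which also decides nothing about reads from neighbouring libraries. Doublets, shared reads and mixed expression therefore remain open, and no biological explanation was tested.

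Arterial and venous scores gave a ratio of 0.833, on the side of rising together, but at percentile 6.30 it lies within what random pairs give, so chance alone could account for it. The 12 clustered mesenchyme-like cells alone do not set it, since without them the ratio was 0.835 at percentile 7.35. Without the 40 cells holding markers of another type, most of them mesenchyme markers and erythroid ones not counted, it was 0.988 at percentile 47.16, so a wider mixture is a candidate explanation. With the pan-endothelial score regressed out of both scores and of the random lists, the ratio was 1.15 at percentile 87.63, so the overall endothelial transcript content of each cell is another candidate explanation. The tests do not separate these explanations, and no biological explanation was tested.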
